A study of Mus musculus with 2 samples.

How the data were processed

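ChIP-seq against H3K4me1 was analysed in 2 biological replicates of E14TG2a.4 mouse embryonic stem cells, numbered as in the labels. The aligner and the peak caller are not given in the sources used here. Per the file headers and read-me lists, the authors deposited narrowPeak lists on mm10 for each replicate, for the pooled replicates and for peaks they kept as replicated, and broadPeak lists on mm9 for each replicate and for the series. The mm10 lists gave each peak a signal value, a −log10 p and a −log10 q, as the authors' caller wrote them. The mm9 lists deposited by the authors gave a signal value, a p-value and a q-value, and their intervals were whole multiples of 200 bp. Signal values, p-values and q-values are the authors' own per peak and were used to rank or filter peaks within a list, to correlate the replicates and to compare X with the autosomes within a list. Per the read-me lists deposited with the samples, the replicate 2 and pooled mm10 lists also drew on 1 file that the replicate 1 list did not, with its role not stated. Every interval of the replicated list was also an interval of the pooled list. No list gave read counts, so depth is unknown and no interval or floor that depends on it was computed. Mean and SD over the replicates describe these 2 libraries only, and with 1 group no test between groups was possible.

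Peak lists were used as deposited. No interval overlapped another of its list. Overlap was counted from 1 bp, and chance overlap was measured with 100 random placements of the intervals of replicate 2 within their chromosome, keeping number and width. Where fewer placements were drawn, for single lists in the genomic distribution, there were 20. Protein-coding genes on mm10 were taken from a RefSeq table of GRCm38.p6, which gave starts and ends but not strands. Strands were taken from GENCODE vM1 for genes on the same chromosome, by symbol for 18392 genes and by synonym for 2166. The remaining 1329 of 21887 genes, Sox1 among them, were left out. As a check of the builds, 74.7% of GRCm38 TSSs had a peak of the mm10 replicated list within 2 kb, against 39.8% of mm9 TSSs. Exons on mm10 were not used here, so the planned split into exon and intron was made with the mm9 lists and GENCODE vM1, and on mm10 gene bodies were kept whole. No coordinate was converted between builds. Chromosome lengths on mm10 were taken as the largest peak or gene end. GC content and the observed to expected CpG ratio came from 500 bp on each side of the mm9 TSS of the same gene, known for 20307 genes, and mappability from the share of 40 evenly spaced 32-mers per 20 kb window that occur once in the mm9 genome.

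Coverage of a gene was the percent of the 20 kb on each side of its TSS that lay in peaks, per replicate. Only the 5' end of each gene record was used as its TSS, so other promoters of a gene were not examined. The 21 gene lists, 17 of symbols and 4 of symbol patterns, and the design, settings and naming rule were fixed before the data were examined. Each list's median was placed among 10000 random lists of the same size matched on deciles of gene length, or 1000 for lists of over 60 genes, with ties split evenly. Percentiles describe these libraries, since genes are not replicates, and no p-value was computed across genes. About 5% of lists would lie outside the bounds by chance. Named genes were the 3 members of each symbol list with the highest mean coverage and up to 2 members without a replicated promoter peak, the highest member of each pattern list, the 10 genes with the highest coverage that were above the 90th percentile in both replicates, and the genes at the 10 widest domains. Members below the median of all genes were named outside this rule, after their values were seen. Some genes that this rule names are not reported here. Domains were replicated peaks joined across gaps of up to 1 kb.

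Alternatives were a 50% reciprocal overlap, a −log10 q of at least 2, the 50000 strongest peaks, the mm9 lists, the pooled list, leaving out each replicate, other windows around the TSS, other matching of random lists and other domain gaps. The use of mm9 lists with GENCODE genes, autosomal genes only and uniquely mappable genes, and of GC matching and uniquely mappable genes for symbol stems, was added after the data were seen. The overlap, placement and random-list functions were tested on simulated data with known answers. In 100 simulated lists of 15 genes, a rise of 20 percentage points in coverage was placed above the bound in 93%, a rise of 10 points in 28%, and no rise in 1%. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.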

Results

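Monomethylation of lysine 4 on histone H3 (H3K4me1), a chromatin mark found at enhancers and on the flanks of promoters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in E14TG2a.4, a male mouse embryonic stem cell line of the 129/Ola strain. The labels name 2 biological replicates, and these form the only group. No control library and no other condition was analysed here, so the comparisons are between genes, regions and replicates of the same cells. The data were the authors' peak lists. On the mm10 genome, 313453 peaks were listed for replicate 1 and 325226 for replicate 2, a mean of 319340 ± 8325 (SD, n = 2). The median peak was 404 bp wide in replicate 1 and 394 bp in replicate 2, and the peaks covered 7.74% and 7.89% of the genome. Peak lists carry no read counts, so the sequencing depth of both replicates is unknown.

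The mark was described for 20558 protein-coding genes by coverage, the percent of the 20 kb on each side of the transcription start site (TSS) that lay in peaks. Median coverage over all genes was 14.7% in replicate 1 and 14.4% in replicate 2. A promoter peak, meaning a peak of the authors' replicated list within 2 kb of the TSS, was present at 15354 genes, or 74.7%. Of the peaks of that list, 91.4% were overlapped by both replicate lists, by at least 1 bp each, and 298 peaks were overlapped by neither. The TSS was the 5' end of the gene record, and other promoters of a gene were not examined. No base was covered in either replicate at 2876 genes. Across genes, which are not independent replicates, coverage in the replicates correlated with a Spearman coefficient of 0.990. The median of a gene list was taken over the per-gene means of both replicates. Its SD was that of the 2 replicate medians, so the list median need not lie between them. The median of each gene list was placed among random lists of the same size matched on gene length. A list was said to stand apart when its median lay above the 97.5th or below the 2.5th percentile of the random medians.

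The list of core and naive pluripotency genes stood above its random lists. Its median coverage was 47.5% ± 1.70 (SD, n = 2), against 18.8% in matched random lists, and it lay above all 10000 of them. Of the 26 genes, 25 carried a promoter peak. Coverage was highest at Klf2, a Krüppel-like factor of the naive state on chromosome 8 from 72319062 to 72321654, with 77.3% ± 2.10. It was followed by Tbx3, a T-box transcription factor, with 74.4% ± 1.92, and Sall4, a zinc finger transcription factor, with 72.7% ± 0.63 (SD, n = 2 for each gene here and in the later paragraphs). Tdgf1, which encodes a NODAL co-receptor, was the member without a replicated promoter peak, although 49.8% ± 4.85 of its window was covered. Nr0b1 (6.04% ± 0.58) and Esrrb (8.08% ± 0.15) lay below 14.63%, the median of all genes for the mean of the replicates. Nr0b1 is on chromosome X, where the median over genes was only 1.06% in replicate 1 and 0.547% in replicate 2. Genes said to lie below the median of all genes, here and in later paragraphs, were named after their values were seen. The 10 formative and primed genes had a median of 47.2% ± 3.66 at percentile 99.84, with 69.2% ± 2.16 at Foxd3, 56.4% ± 2.84 at Lef1 and 48.6% ± 1.39 at Zic2. Dnmt3a, the de novo DNA methyltransferase gene, had 32.3% ± 5.05 and no replicated promoter peak at the TSS used, the 5' end of its record. Sox3, also on chromosome X, and Fgf5 lay below the median of all genes. The formative list fell to percentile 96.91 with windows of 50 kb and to 97.23 with gene bodies in place of TSS windows, which ended its call.

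**Figure D1:**
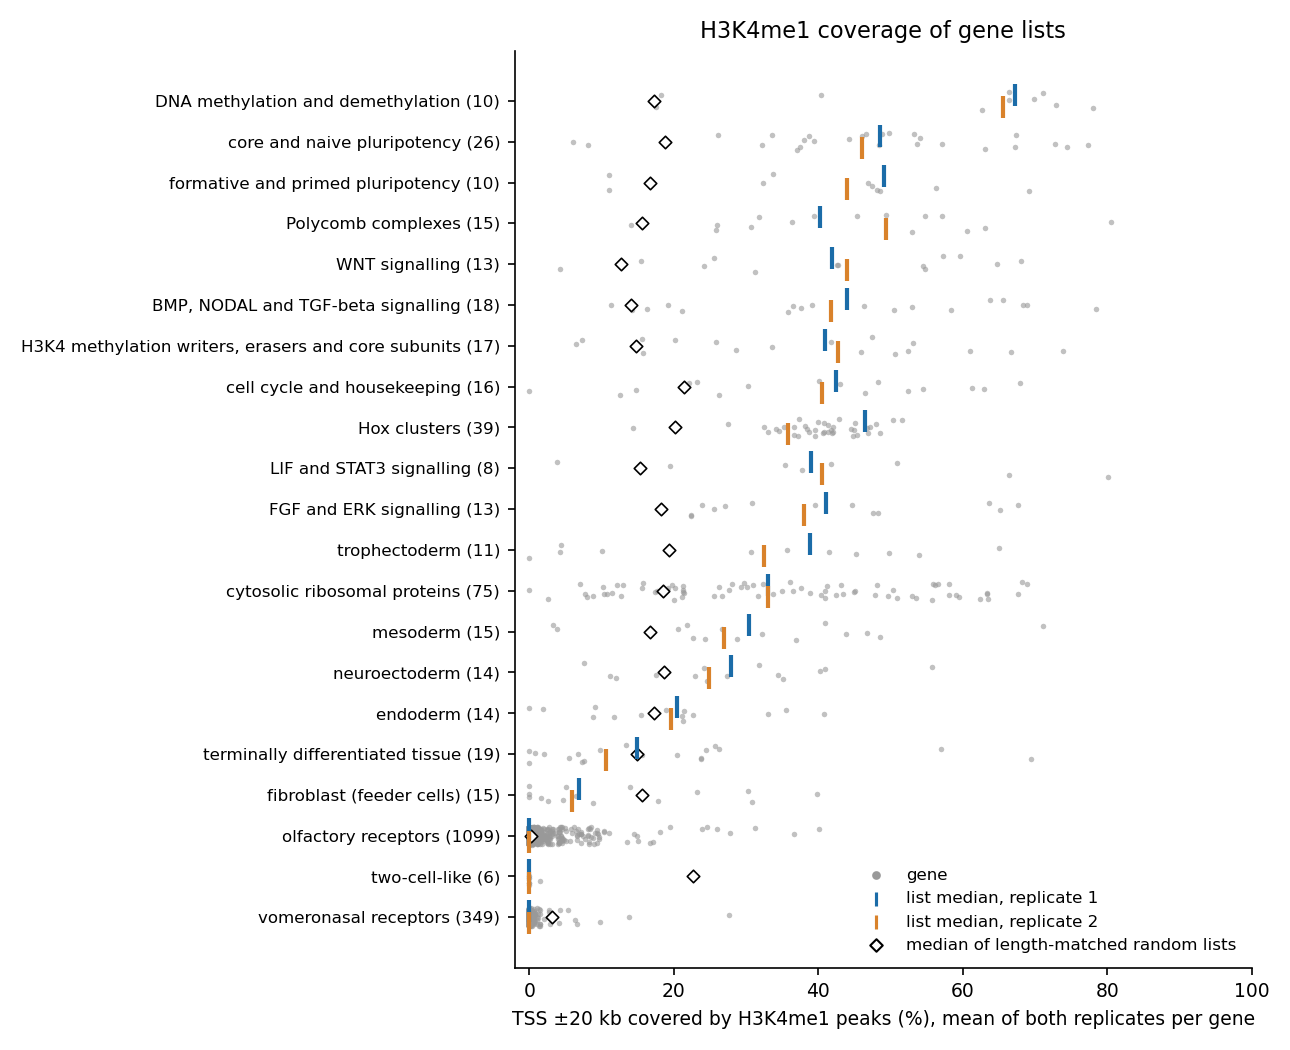
Percent of the 20 kb on each side of the TSS covered by H3K4me1 peaks (x axis) for the genes of 21 lists (y axis, number of measured genes in brackets). Grey points are genes as the mean of both replicates, coloured ticks are the list medians in each replicate, and diamonds are the medians of length-matched random lists. The pluripotency list sits at 47.5% against 18.8% in its random lists, and the vomeronasal receptors at 0%.

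The lists of 4 signalling pathways that act in embryonic stem cells stood above their random lists as well, but some members did not exceed the median of all genes. The LIF and STAT3 list had a median of 39.8% ± 1.14 (percentile 98.59), and all 8 genes had a promoter peak. Socs3, a feedback inhibitor of STAT3 signalling on chromosome 11 from 117966079 to 117970336, reached 80.2% ± 4.47, and the kinase genes Pim1 and Pim3 reached 66.4% ± 0.62 and 50.9% ± 0.94. In the WNT list the median was 42.8% ± 1.47 (percentile 100), with promoter peaks at all 13 genes. Ctnnb1, which encodes beta-catenin, had 68.0% ± 3.17, the feedback inhibitor Axin2 had 64.8% ± 3.57, and Tcf7l1 had 59.6% ± 2.12. The BMP, NODAL and TGF-beta list had a median of 42.8% ± 1.51 (percentile 99.98) and promoter peaks at all 18 genes, led by the inhibitory SMAD gene Smad7 with 78.4% ± 0.65. The NODAL antagonist genes Lefty1 and Lefty2 followed with 69.0% ± 2.63 and 68.3% ± 0.65. The FGF and ERK list had a median of 39.6% ± 2.21 (percentile 98.58), with 67.6% ± 1.30 at Spry4, 65.1% ± 0.30 at Etv4 and 63.7% ± 1.16 at Etv5. Of its 13 genes, only Spry2 lacked a replicated promoter peak, with 30.8% ± 1.81 of its window covered. Below the median of all genes lay Jak1 (3.85% ± 0.31) in the LIF list, Nkd1 (4.32% ± 1.69) in the WNT list and Smad5 (11.3% ± 0.34) and Smad1 (14.2% ± 3.21) in the BMP list, and 0 genes of the FGF list. With random lists matched on GC content, the LIF list fell to percentile 95.63 and the FGF list to 96.61. The LIF list also lost its call with gene bodies (97.3) and with uniquely mappable genes (93.7), and the FGF list with 50 kb windows (95.5) and with the mm9 lists (92.8).

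Genes of DNA methylation and demethylation had the highest median of the 21 lists with 20 kb windows, but not with 5 kb windows, where they had 49.2% and the formative list 59.4%. Their median was 66.4% ± 1.14 (percentile 100), against 17.3% in random lists. Zfp57, whose zinc finger protein maintains imprinted methylation, had 78.0% ± 1.13, the NuRD subunit gene Mbd3 had 72.9% ± 4.46, and Uhrf1, a cofactor of maintenance methylation, had 71.1% ± 1.42. Tet2 was the member of this list without a replicated promoter peak and had 40.4% ± 5.28. Polycomb genes had a median of 45.4% ± 6.44 (percentile 99.98), and all 15 carried a promoter peak. Jarid2, a subunit of a Polycomb repressive complex, on chromosome 13 from 44730774 to 44921643, had 80.6% ± 0.08, Phc1 had 63.1% ± 0.73 and Cbx7 had 60.6% ± 1.67. Among the writers, erasers and core subunits of H3K4 methylation, the median was 41.8% ± 1.21 (percentile 99.98). The demethylase gene Kdm5b had 73.9% ± 0.92, and the methyltransferase genes Setd1b and Kmt2b had 66.7% ± 2.96 and 61.0% ± 0.80. Dpy30, a core subunit gene, lacked a replicated promoter peak and had 33.6% ± 0.77. Bmi1 (14.1% ± 0.90) in the Polycomb list lay below the median of all genes. So did Kdm5c (6.53% ± 0.20), on chromosome X, and Ncoa6 (7.24% ± 1.51) in the H3K4 list. Among genes with at least 90% unique sequence, the Polycomb list fell to percentile 95.9, which ended its call.

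Housekeeping and cell cycle genes, ribosomal protein genes and Hox genes also stood above their random lists. The housekeeping list had a median of 41.5% ± 1.32 (percentile 99.10), with 68.0% ± 2.17 at Actb, 62.9% ± 4.61 at Cdk1 and 61.3% ± 2.12 at Gapdh. Hprt, the purine salvage enzyme gene on chromosome X from 52988078 to 53021660, was the exception in this list. It had 0% in both replicates and no promoter peak. The parental line E14TG2a is known to lack HPRT activity, and the peak lists cannot show whether the locus is intact in these cells. Of 40 sampled 32-mers of the Hprt window, 80.0% occurred once in the mm9 genome. B2m also lay below the median of all genes. The 75 cytosolic ribosomal protein genes had a median of 32.3% (percentile 99.90), with 13 below the median of all genes. All 39 Hox genes had a promoter peak, with a median of 40.9% ± 7.62 (percentile 99.98) and the highest value at Hoxa9, 51.7% ± 7.51, and only Hoxd1 lay below the median of all genes. Hox windows overlap within the clusters, so these genes are not independent, and the Hox list lost its call with 5 kb windows (96.8) and with random lists matched on the number of neighbouring TSSs (90.03). The housekeeping list lost it with 50 kb windows (96.3), gene bodies (80.7) and uniquely mappable genes (94.6), and the ribosomal list with 50 kb windows (97.4) and gene bodies (96.8).

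Lineage marker lists did not stand apart, although most of their genes carried promoter peaks. Of all genes, 74.7% carried such a peak, and the endoderm list, with 11 of 14, was near that share. Promoter peak counts of this and other lists were not placed among random lists. The mesoderm list had a median of 28.7% ± 2.51 (percentile 90.04) with promoter peaks at all 15 genes, and Tbx6 had 71.1% ± 2.11, Meox1 48.6% ± 2.42 and Eomes 46.7% ± 1.52. The neuroectoderm list had 26.0% ± 2.15 (percentile 77.7) with promoter peaks at all 14 measured genes, and Pax6 had 55.7% ± 4.81, Six3 41.0% ± 4.73 and Nes 40.3% ± 2.86. In the trophectoderm list the median was 35.6% ± 4.48 (percentile 93.8), with 65.0% ± 1.57 at Tfap2c, 53.9% ± 2.31 at Tead4 and 49.8% ± 1.09 at Gata3, and no coverage at the placental hormone gene Prl3d1. The endoderm list had 20.1% ± 0.59 (percentile 63.9), with 40.8% ± 2.81 at Gsc, 35.5% ± 2.90 at Hnf4a and 33.0% ± 3.22 at Foxa2, 1.93% ± 0.33 at Afp and no coverage at Dab2. With random lists matched on neighbouring TSSs, the mesoderm, neuroectoderm and trophectoderm lists rose above the bound, at percentiles 98.4, 98.0 and 99.6. With gene bodies, the neuroectoderm and trophectoderm lists did so at 99.48 and 98.95.

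Markers of fibroblasts and of differentiated tissues did not stand apart from their random lists. Fibroblast genes, included because embryonic stem cells can be grown on feeder fibroblasts, had a median of 6.42% ± 0.71 (percentile 4.41). Pdgfrb had 39.8% ± 2.56, Thy1 30.8% ± 1.29 and Col1a1 30.2% ± 5.98, and the matrix genes Col3a1 and Dcn had no covered base. Genes of terminally differentiated tissues had a median of 13.3% ± 3.06 (percentile 43.2). Among them Insl3 had 69.4% ± 5.08, the muscle creatine kinase gene Ckm 57.0% ± 6.54 and Gfap 26.2% ± 3.68, whereas the albumin gene Alb and Pmch had none. The fibroblast list fell below the lower bound with the mm9 lists (1.22) and with uniquely mappable genes (1.45).

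Few peaks were listed around genes of the 2-cell-like state and sensory receptor genes. Of the 10 genes of the 2-cell-like list, 6 could be measured and 5 of these, among them Gm4340 and Usp17la, had no covered base. Zfp352 had 1.55% in replicate 1 and 1.44% in replicate 2, none of the 6 had a promoter peak, and the list median of 0% lay at percentile 0.24. Of the 32-mers sampled in each of these windows, between 7.5% and 75% occurred once in the mm9 genome, against a median of 92.5% over all genes, so a lack of peaks there does not show a lack of the mark. The same limit applies to the receptors, of which 15 of 349 vomeronasal and 173 of 1099 olfactory genes had windows with at least 90% unique 32-mers. Promoter peaks were found at 5 of 349 vomeronasal receptor genes, whose median was 0% (percentile 0). They were found at 41 of 1099 olfactory receptor genes, whose median was also 0%. Windows of neighbouring receptor genes can overlap, so these genes are not independent. The highest values among the receptors were 27.7% ± 0.72 at Vmn1r1 and 40.2% ± 1.24 at Olfr90. The olfactory list lay at percentile 21.25, but 86.0% of its genes were in the shortest decile of genes, of which they made up 46.0%, and random lists drawn without them were not tested. It lay at percentile 0 with 50 kb windows, with matching on neighbouring TSSs, with the mm9 lists and among its uniquely mappable genes, and between 8.25 and 50 in the other settings. With random lists matched on GC content the 2-cell-like list moved to percentile 24.7 and the vomeronasal list to 50, which ended both calls; the 2-cell-like call also ended with the mm9 lists (5.62), and the vomeronasal call with 5 kb windows (6.7) and gene bodies (23.4).

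Over all protein-coding genes, the highest coverage was found at the threonine aldolase gene Tha1 on chromosome 11 from 117867949 to 117873526, with 91.5% ± 0.68. Itpk1, an inositol phosphate kinase gene, had 90.8% ± 0.80, and the kinase gene Fgr had 88.6% ± 2.06. Cisd3, Sulf2, Actn4, Pmepa1, Tjp3 and Pip5k1c were also among the 10 highest, with values from 87.3% ± 1.47 down to 85.1% ± 0.60. The TSSs of Tjp3 and Pip5k1c, at 81291581 and 81292835 on chromosome 10, are neighbours. Their windows are largely the same sequence, so they stand for a single region. By the naming rule, all of these had to lie above the 90th percentile of genes in both replicates.

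With gaps of up to 1 kb joined, the widest H3K4me1 domains of the replicated list lay within Pitpnc1, which encodes a phosphatidylinositol transfer protein, and Jarid2. Neither gene held a domain among the 10 widest of replicate 1, of which the narrowest was 71679 bp, whereas in replicate 2 the domains spanned 101054 bp at Pitpnc1 and 134585 bp at Jarid2. When replicated peaks were joined across gaps of up to 1 kb, 110522 domains resulted, of which 4142 were at least 10 kb and 992 at least 20 kb wide. That of Pitpnc1 spanned 134961 bp, on chromosome 11 from 107334125 to 107469085, of which 88.0% lay in peaks of replicate 1 and 90.05% in peaks of replicate 2. A domain of 134914 bp lay within Jarid2, on chromosome 13 from 44734266 to 44869179, and a domain of 127116 bp within the corepressor gene Ctbp2, on chromosome 7 from 132987860 to 133114975. The next lay outside protein-coding genes, with 99207 bp on chromosome 15 from 62036160 to 62135366. Its centre lay 100421 bp from the nearest protein-coding TSS, that of Myc. Non-coding genes were not examined, so the domain may lie on one. Tns3, Kat6b, Zmynd8, Arid1a and Plekha7 also held domains among the 10 widest, from 96986 bp down to 77104 bp. The number of domains of at least 10 kb depended on the gap, with 268 when only touching peaks were joined, 8570 at 3 kb and 11289 at 10 kb. Of the 10 widest, 8 were also among the 10 widest of the pooled list, 6 in replicate 1 and 8 in replicate 2. Only 1 was so without joining, 3 with gaps of 3 kb and 1 with gaps of 10 kb. Pitpnc1 was not among the 10 widest at these other gaps, and Jarid2 only with gaps of 3 kb, at rank 6.

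**Figure D2:**
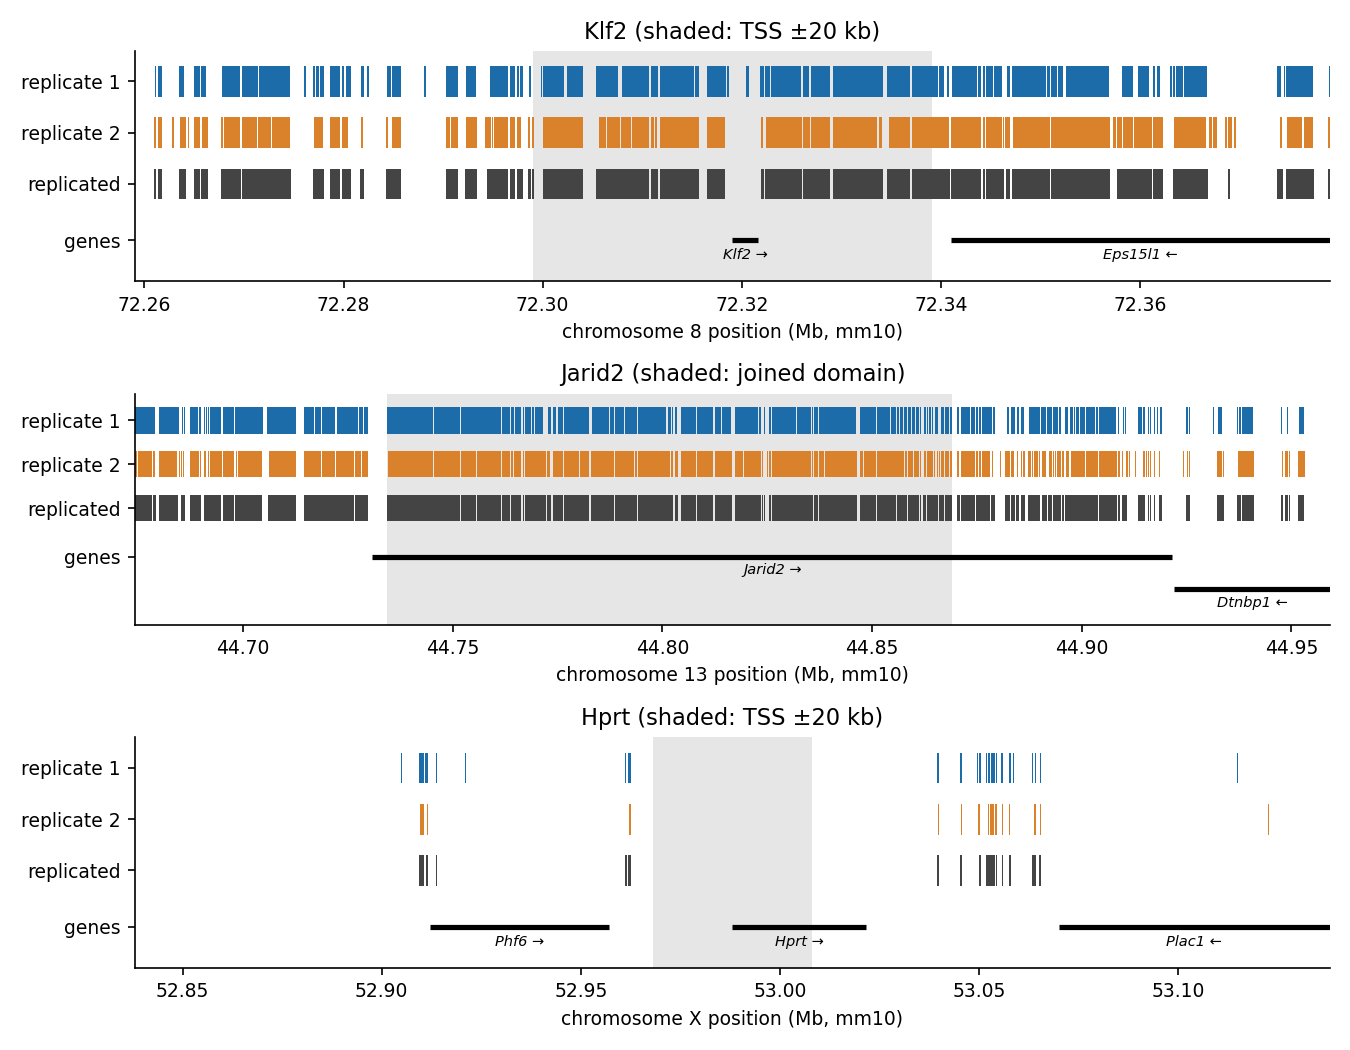
Peaks of replicate 1, replicate 2 and the authors' replicated list (rows of bars) and protein-coding genes (black lines, arrows give the strand) at Klf2, Jarid2 and Hprt, by mm10 position in Mb (x axis). Shading marks 20 kb on each side of the TSS of Klf2, with 77.3% covered, and of Hprt, with 0% covered, and the joined domain of 134914 bp at Jarid2.

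Around TSSs the mark formed a shoulder on each side of a gap. In replicate 1, averaged over TSSs, 20.3% of the sequence was covered in the 100 bp bins next to the TSS. The share was 40.4% in the highest upstream bin, starting 500 bp upstream, and 46.8% in the highest downstream bin, ending at 1200 bp. In replicate 2 the values were 15.6%, 35.0% and 42.0%. The gap was deepest at CpG-rich promoters. In the tertile of genes with the highest CpG ratio, 10.1% of the sequence was covered at the TSS and 67.2% downstream in replicate 1. The shares were 7.25% and 61.6% in replicate 2. In the tertile with the lowest CpG ratio there was no gap, with 20.6% at the TSS and 21.7% downstream in replicate 1 and 17.8% and 18.5% in replicate 2. At 5 kb downstream, the replicates differed little, with 23.7% and 24.4% of the bin sequence covered over all TSSs. The downstream to TSS ratio was 2.43 in the replicated list, and 2.30 and 2.69 in the replicates.

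**Figure D3:**
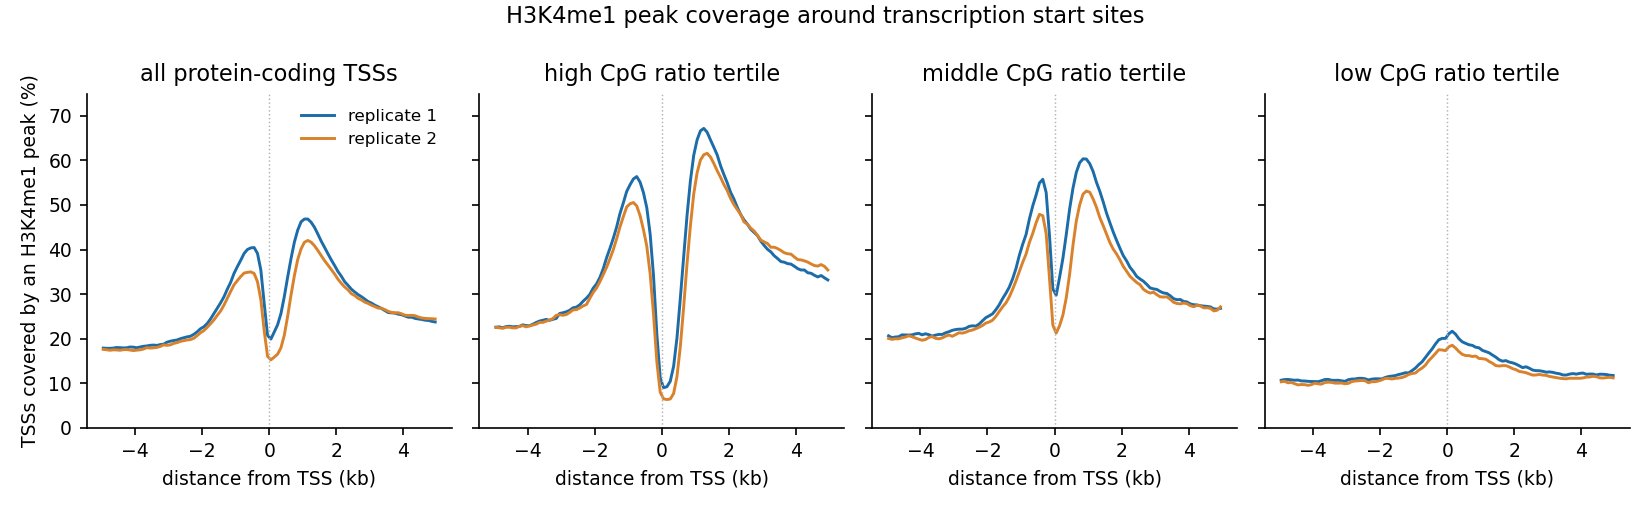
Percent of the sequence of 100 bp bins covered by H3K4me1 peaks, averaged over protein-coding TSSs (y axis, labelled as TSSs covered). Bins are ordered by distance from the TSS in kb (x axis, downstream positive). Panels show all genes and tertiles of CpG ratio, with 1 line per replicate. At CpG-rich TSSs coverage falls to 10.1% and 7.25% and rises to 67.2% and 61.6% downstream, while CpG-poor TSSs show no gap.

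Peaks were concentrated at promoters and in protein-coding genes; non-coding genes were not separated. Of the sequence in replicated peaks, 5.72% lay within 1 kb of a TSS, against 1.60% in random placements, a 3.58-fold enrichment. Gene bodies outside promoters held 59.7% (1.53-fold), and sequence outside protein-coding genes held 34.6% against 59.4% (0.582-fold). The promoter share exceeded, and the share outside genes fell below, every one of 100 random placements (one-sided permutation p = 0.0099, the smallest these placements can give). Promoter shares were 6.30% in replicate 1 and 5.09% in replicate 2. In the mm9 lists, where exons could be separated, exons held 6.99% and 6.93% of the peak sequence in the replicates, each 2.54-fold more than in random placements, and introns held 50.2% and 52.3%. The median peak centre of the replicated list lay 21056 bp from the nearest TSS, against 76278 bp for a random placement, and 14.9% of the peaks lay over 100 kb away.

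Few peaks were listed on the X chromosome. It carried 31.5 peaks per Mb in replicate 1 and 29.5 in replicate 2, against autosome means of 126.9 and 132.0, a ratio of 0.236 ± 0.017 (SD, n = 2). The lowest autosome, chromosome 3, had 87.2 and 91.8 peaks per Mb, and the highest, chromosome 11, had 200.4 and 204.6. Of the 909 X genes, 42.5% had a promoter peak, and their median coverage was 1.06% in replicate 1 and 0.547% in replicate 2. Chromosome 11 genes had medians of 26.4% and 25.5%. None of the 19 measured genes of chromosome Y had a promoter peak.

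**Figure D4:**
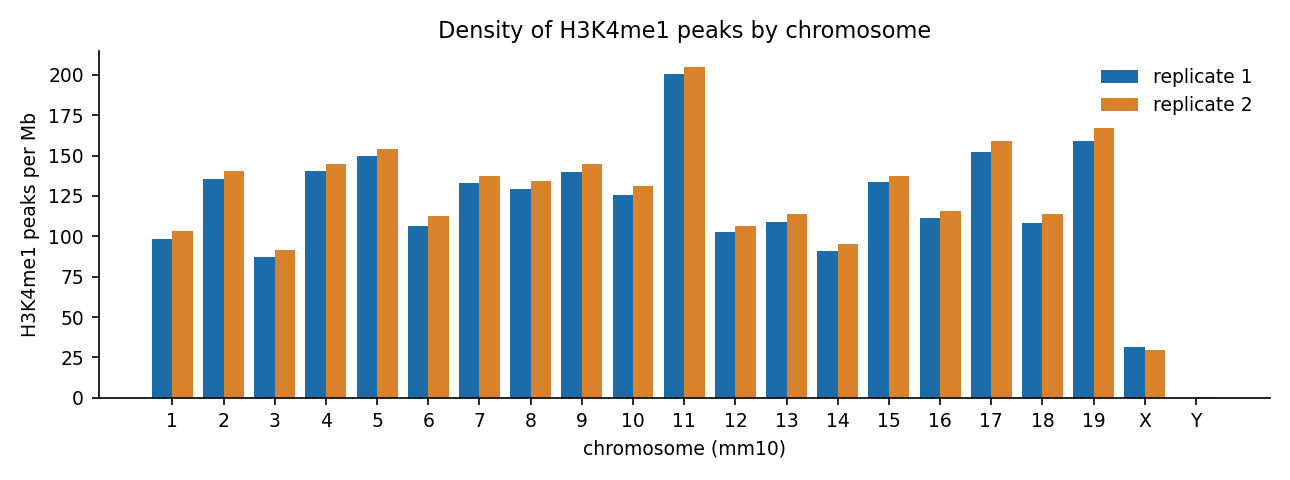
H3K4me1 peaks per Mb (y axis) on each mm10 chromosome (x axis), with 1 bar per replicate. Chromosome X has 31.5 and 29.5 peaks per Mb, below the lowest autosome, chromosome 3, with 87.2 and 91.8.

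The replicates shared most of their marked regions. At a minimum overlap of 1 bp, 82.8% of the peaks of replicate 1 were overlapped by replicate 2, against 17.1% when the peaks of replicate 2 were placed at random within chromosomes. Of the peaks of replicate 2, 79.4% were overlapped by replicate 1, against 13.8%, and shared sequence made up 0.679 of the union (Jaccard index), against 0.0473. Each value exceeded all 100 placements (one-sided permutation p = 0.0099, the smallest these placements can give). The placements kept only peak number and width per chromosome. They therefore cannot separate agreement of these replicates from a concentration of peaks near genes in both. The authors' signal value, used to rank peaks within a list, correlated across 259479 shared peaks with a Spearman coefficient of 0.594 and a Pearson coefficient of 0.622 on the log10 scale. Recovery in the replicated list rose with strength, except that the second decile of replicate 1 had 65.4%. The share overlapped went from 67.3% and 58.8% in the weakest decile of replicates 1 and 2 to 100% in the strongest of both. That list was derived from both replicates, so it is not independent of them. The other replicate alone overlapped 61.0% and 50.2% of the weakest decile of replicates 1 and 2, and 99.98% of the strongest of both. The replicated list held 73.1% of the pooled peaks, those kept having a median width of 692 bp and those not kept 219 bp. With 50% reciprocal overlap the shared shares were 53.4% and 51.5%.

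**Figure D5:**
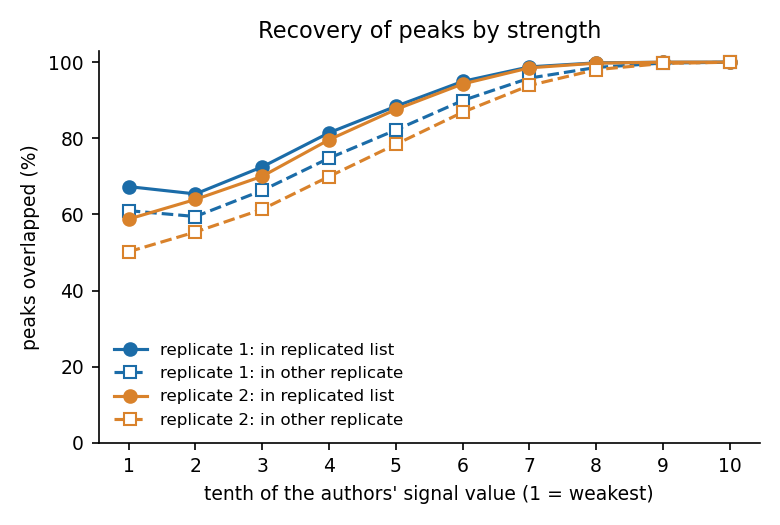
Percent of the peaks of each replicate overlapped by at least 1 bp (y axis) by the authors' replicated list (filled circles) or by the other replicate (open squares), by decile of the authors' signal value (x axis, 1 is the weakest). The share in the replicated list rises from 67.3% and 58.8% to 100%.

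The mm9 lists of the same replicates held fewer and wider peaks. Replicate 1 had 112491 and replicate 2 had 120124, a mean of 116308 ± 5397 (SD, n = 2), with median widths of 1800 and 1600 bp. They covered 11.93% and 12.04% of the genome, and 91.8% of the peaks of replicate 1 were overlapped by replicate 2. The chromosome with the most peaks per Mb was chromosome 11 in both replicates, as on mm10, and the X to autosome ratio was 0.234 in replicate 1 and 0.217 in replicate 2.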

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

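No test was run on the values in this part. Peaks were found on unplaced scaffolds of mm10, which the gene, chromosome and domain comparisons left out, and 2 scaffolds had more peaks in both replicates than the 95% upper limit of a count of 0 (2.996 peaks). No expected number of peaks was computed for a scaffold, so the counts show only that peaks were listed there. The first had 5 peaks in replicate 1 and 7 in replicate 2, and the second had 17 in each replicate.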

How the results depend on the processing

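The alternatives that use mm9 lists with GENCODE genes, autosomal genes only or uniquely mappable genes, and those for symbol stems, were chosen only after the data were seen. Replicate overlap stayed above all placements in the 5 alternatives run, with 53.4% to 91.8% of the peaks of replicate 1 shared. Promoter enrichment was 2.99-fold to 3.94-fold in the alternatives to the replicated list, and 2.81-fold in the mm9 list of replicate 2 placed outside runs of N. The X to autosome ratio of peaks per Mb ranged from 0.217 in the mm9 list of replicate 2 to 0.254 in the mm9 series list. With a −log10 q of at least 2, median width was 419 bp and 7.69% of the genome was covered, because weaker peaks were left out. The mm9 lists gave 116308 peaks of 1700 bp covering 11.98% (means of the replicates) and, in the series list, a downstream to TSS ratio of 2.05; the cause was not tested. The Spearman coefficient of peak strength was 0.632 with −log10 p. Promoter peaks were found at 71.3% of genes within 1 kb and 77.9% within 5 kb, as the window sets. Domains of at least 10 kb numbered 268 without gaps, 8570 with gaps of 3 kb and 11289 with gaps of 10 kb, as joining sets. Of the 21 gene lists, 12 lay above the random lists, and 8 to 14 did under the alternatives. The 2 below became 1 with 5 kb windows, 1 with gene bodies and 0 with GC matching, and 3 with 50 kb windows, with matching on TSS number, with the mm9 lists and among uniquely mappable genes, and the cause was not tested. Core pluripotency, WNT, BMP, H3K4 and DNA methylation lists kept their call in all 14 settings. Of the symbol stems, 17 lay above and 23 below the random lists, against 8 and 10 with GC matching and 7 and 17 among uniquely mappable genes; the cause was not tested. The 2-cell-like list has no value among uniquely mappable genes. None of these results reversed, but the X to autosome ratio of median peak signal, which is not among them, was 0.871 and 0.881 on mm10 and 1.403 and 1.44 on mm9. No paired analysis was possible because there was 1 group. Depth is unknown, so its effect on these values was not measured.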

Other observations

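The grouping of genes by symbol stem with its alternatives and the tests of reads not placed uniquely at Hprt, of a single X copy, of more peaks in replicate 1 and of a step of the mm10 lists were chosen only after the result was seen. Genes were grouped by the letters that open their symbols, and 104 stems had at least 20 genes. Of these stems, 17 lay above and 23 below length-matched random lists. Genes of a stem can be neighbours with overlapping windows, whereas random genes were drawn without regard to position, so genes of a stem are not independent. Zbtb genes, which encode BTB domain zinc finger proteins, had a median coverage of 42.7% ± 1.97 (SD, n = 2), and 39 of 40 carried a promoter peak. Polr genes, encoding RNA polymerase subunits, had 35.8% ± 0.260, and Mrpl genes, encoding mitochondrial ribosomal proteins, had 35.1% ± 0.431 with promoter peaks at all 49. As for the gene lists, the median is over per-gene means and the SD is that of the replicate medians. For Mrpl these replicate medians were 34.7% and 34.1%. Cyp genes, encoding cytochrome P450 enzymes, had 1.197% ± 0.410, and 41 of 99 had no covered base. Keratin genes (Krt) had 4.40% ± 0.251, although Krt42 reached 80.5%. None of the 25 prolactin family genes (Prl) carried a promoter peak, but the median share of unique 32-mers in their windows was 80%. With random lists matched on GC content, 8 stems lay above and 10 below, and the Prl stem moved from percentile 0 to 48.45, which ended its call. Among genes with at least 90% unique sequence, 7 stems lay above and 17 below, and the Mrpl stem moved from percentile 99.8 to 95 and the Cyp stem from 0 to 6.7, which ended both calls; Prl stayed at percentile 0, with 4 genes left.

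No covered base lay within 20 kb of the Hprt TSS in any of the 7 lists, and the stretch without a peak in either replicate ran over 76982 bp, on chromosome X from 52962534 to 53039515 (mm10). Reads not placed uniquely cannot be the whole cause, since only 0.435% of 460 CpG-rich autosomal genes with a like share of unique 32-mers had no covered base (Wilson 95% interval 0.119 to 1.57), although the planned test, the share of unique 32-mers of the Hprt window (80.0%, 65.2 to 89.5), had decided nothing. Sparse peaks on X stay open, alone or together with such reads, since 6.25% of the other 128 CpG-rich X genes had no covered base either (3.201 to 11.8). A deletion may also account for it, since the parental line E14TG2a is known to lack HPRT activity, but the stretch ranked 16 of 129 CpG-rich X genes, and 22 and 25 in the single replicates, which met the bound set beforehand against a deletion (outside the longest 10%). That bound was judged wrong only after the rank was seen. A deletion sets no minimum against other X genes, whose stretches are long where peaks are sparse, so the rank decides nothing about it.

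The X chromosome carried fewer peaks per Mb than every autosome. Bootstrap bounds in this paragraph come from resampling genes, which are not replicates, and are the lowest and highest of both replicates. Fewer genes on X cannot be the whole cause, since CpG-rich X genes had at most 0.253 of the median coverage of autosomal ones (bootstrap bounds 0.143 to 0.309), nor can reads not placed uniquely, since the ratio was at most 0.278 (0.165 to 0.347) among genes with at least 95% unique sequence. A single X copy in a male line is a candidate explanation, since the strongest promoter peaks of CpG-rich genes had a median −log10 p on X of at most 0.456 of that on the autosomes (0.364 to 0.503). The same lower value could come from any weaker marking of X, which was not tested. In the mm9 lists the median signal of X peaks was above the autosomes, with ratios of 1.403 and 1.44, whereas on mm10 the ratios were 0.871 and 0.881.

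Coverage of the 200 bp around TSSs was 1.30 times as high in replicate 1 as in replicate 2 (bootstrap bounds over TSSs 1.28 to 1.32). Such bounds, also for the other TSS ratios below, describe the TSSs in these libraries and not the spread between libraries. More peak sequence in replicate 1 is argued against, since it covered 0.981 of the genome length covered in replicate 2. Leaving out each autosome in turn gave 0.979 to 0.983, which is not a confidence interval. Weak peaks are argued against by a ratio of 1.64 (1.57 to 1.72) among the 50000 strongest peaks, and a step of the mm10 lists alone by a ratio of 1.33 (1.30 to 1.34) in the mm9 lists. Differences between the libraries stay open, as does the additional source file of the mm10 list of replicate 2, whose role is not stated and whose use for the mm9 lists is not given in the sources used here; no biological explanation was tested because the replicates form 1 group.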
